A study of Mus musculus with 10 samples.

How the data were processed

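RNA was measured in 10 libraries of intestinal epithelial cells from C57BL/6 mice aged 14 weeks, per the labels. Of these, 4 libraries came from wild-type (WT) mice without segmented filamentous bacteria (SFB), 3 from WT mice colonized with SFB and 3 from IECΔCDC42 mice colonized with SFB. SFB are gut bacteria that attach to epithelial cells, CDC42 is a small GTPase that organizes actin and cell polarity, and the IECΔ in a strain's name marks a deletion in intestinal epithelial cells. The labels give no intestinal segment, sex, batch or day, and do not say whether each library is a separate animal. The p-values therefore measure the spread between these libraries, part of which is possibly technical. By the library numbers in the sample titles, all libraries with SFB come before all those without. Any effect tied to that order cannot be told apart from SFB. Per the labels' protocols, RNA was taken up in Trizol and made into libraries with an Illumina TruSeq kit for paired-end sequencing. Those protocols name both poly-A selection and ribosomal RNA depletion for all samples, so which of these was used is not given in the sources used here.

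The authors deposited 2 tables of normalized counts per gene, a never-negative signal that the file headers describe as kallisto counts normalized with DESeq2. The first table holds the 4 WT libraries without SFB and the 3 WT libraries with SFB. The second table holds the same 4 libraries and the 3 IECΔCDC42 libraries. Per the submitters' processing notes, bcl2fastq 2.20, kallisto 0.44.0 and sleuth were used, and the notes list the builds GRCh38 and GRCm38 without saying what each served for. The annotation release and any use of strand are not given in the sources used here, so reads of overlapping or antisense genes were possibly not separated. Each table lists 35251 entries by gene symbol, of which 34683 (98.39%) match a symbol of GENCODE M21. Of the symbols, 26 had been turned into dates, as spreadsheets do with septin and march genes, and these were left as they stand. Positions given in the text are those of GENCODE M21 on GRCm38 and were not needed for any test.

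The 4 shared libraries hold different values in the 2 tables, so the tables were normalized separately. The difference was 1 factor per gene times 1 factor per library, to a largest residual of 9.9e-15 on the log scale over 18326 genes. These factors were used to put the IECΔCDC42 libraries on the scale of the first table wherever levels of all 3 groups are set side by side, and such levels are called rescaled. For 61 genes with a mean of at least 1 the shared libraries gave no factor. Totals of normalized counts were 50814400 to 65071600 per library. Whole reads were looked for in the values under 30, and 67.0 to 71.9% of these came out whole within 0.1, which is too few to recover read counts. Depth in reads is therefore known only roughly, and count tests were not run.

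Values were tested as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3), for genes with a mean of at least 1 over the libraries in the test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The pseudocount of 1 understates the change of low genes. The tests had been planned for counts or for normalized values before the data were examined, and the branch for normalized values was used. The comparisons WT with SFB against WT without SFB, and IECΔCDC42 with SFB against WT without SFB, were each fitted within 1 table. The comparison of IECΔCDC42 with WT, both with SFB, was the difference of these log2 fold changes divided by the root of their summed squared SEs, with a two-sided normal p. Its SE is too large because both share the controls, and its normal tail makes very small p-values of single genes too small, so those are not printed. The list p-values of this comparison were computed from the same statistics, so very small ones are possibly too small as well. The normal tail also matters near the threshold, where 6419 genes passed with it and 4611 with a t distribution. Log2 fold changes are given with the SE of the fit, and levels as mean ± SD.

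The groups, the 36 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, Cdc42 and 12 preset genes (Saa1, Saa2, Reg3g, Reg3b, Nos2, Duox2, H2-Aa, H2-Ab1, Cd74, Fut2, Lyz1 and Lgr5) whether or not they pass. It adds the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50, leaving out predicted models, pseudogenes and immunoglobulin or T-cell receptor segments. It further adds up to 4 members with the smallest p from each list that passed or had at least 3 members past the threshold. Other list members are named as examples of their list and were chosen after their values were seen. Some genes that the rule takes are not reported here. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 (cameraPR for the difference of comparisons), adjusted over the lists. With a correlation estimated for each list instead, 0 lists passed in any comparison, and that adjusted p stands beside each list call. The α-defensin genes are near-identical copies that share reads, so their single values are uncertain.

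The scripts were tested on simulated data with known changes. The simulated genes were drawn independently of each other, and genes of similar level shared 1 spread, so the rates below possibly flatter the real data. At simulated folds of 1.5, 2, 4 and 8, the test of WT with SFB against WT without recovered 59.2, 69.4, 81.6 and 87.8% of changed genes, with 3 false calls among 19807 genes. The test of IECΔCDC42 with SFB against WT without recovered 59.2, 63.3, 83.7 and 91.8%, with 5 false calls among 19892 genes. The difference of the comparisons recovered 44.9, 57.1, 81.6 and 85.4%, with 1 false call among 19604 genes. Alternatives covered scaling, filter, pseudocount, variance model, threshold, set test, a term for Y-linked RNA, 1 fit over all libraries on 1 scale, and leaving out each library. The term for Y-linked RNA, the single fit, the variance models, quantile normalization and a t distribution for the difference of comparisons were added after seeing the data. Other splits of the libraries were counted as a check on chance. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.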

Results

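The series asked how an epithelial commensal communicates with the host through endocytosis, going by its title, and the tables set 3 groups of intestinal epithelial cells side by side. Group sizes were 4 WT libraries without SFB, 3 WT libraries with SFB and 3 IECΔCDC42 libraries with SFB, with totals of 50814400 to 65071600 normalized counts per library. Libraries of 1 group correlated at Spearman rho 0.987 to 0.992 across genes. Between groups rho was 0.976 to 0.986 for WT without and with SFB, 0.946 to 0.958 for WT and IECΔCDC42 with SFB, and 0.932 to 0.951 for WT without SFB and IECΔCDC42. The Y-linked genes Ddx3y and Eif2s3y were at 1816 to 2386 and 1824 to 2035 normalized counts in 4 libraries, namely replicates 1 and 2 of both groups with SFB. In the other 6 libraries, which include all 4 without SFB, they were at 1.95 to 12.4 and 2.92 to 12.2.

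**Figure D1:**
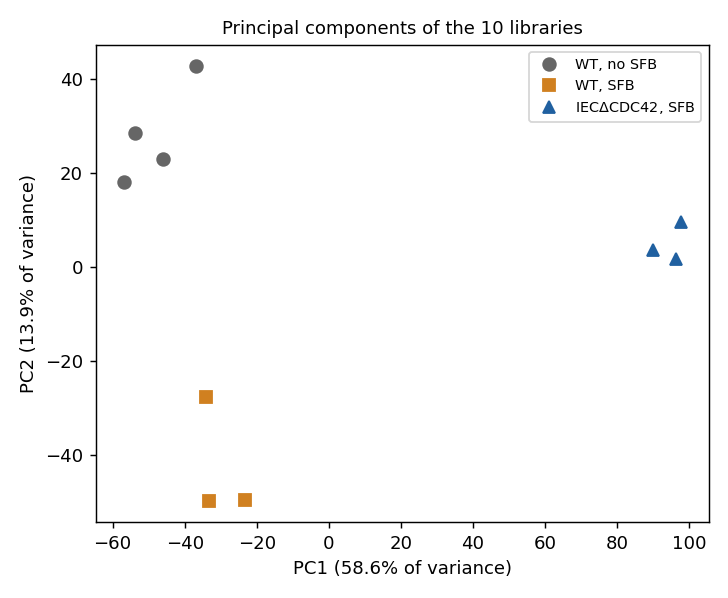
Principal components 1 and 2 of log2(normalized count + 1) over 15906 genes with a mean of at least 10, 1 point per library coloured by group, with the IECΔCDC42 libraries rescaled to the first table. Component 1 (58.6% of the variance) separates the 3 IECΔCDC42 libraries (90.1 to 97.7) from the 7 WT libraries (−56.9 to −23.3), and component 2 (13.9%) separates WT without SFB (18 to 42.7) from WT with SFB (−49.8 to −27.7).

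Cdc42, the targeted gene (chromosome 4, 137319696 to 137357720, minus strand, GRCm38), was lower in the IECΔCDC42 libraries by an amount that did not pass the test. Its rescaled normalized counts were 16684, 19444 and 17084 in IECΔCDC42, 24716, 21952 and 19851 in WT with SFB, and 18015, 22128, 20008 and 21250.2 in WT without. The log2 fold change was −0.32 ± 0.14, adjusted p = 0.0618 against WT with SFB and −0.20 ± 0.10, adjusted p = 0.128 against WT without. With library totals set equal it was −0.44 (adjusted p = 0.000535) and −0.39 (adjusted p = 0.00195), and in 1 fit over all libraries against WT with SFB it was −0.32 (adjusted p = 0.0335). A t distribution for the difference gave adjusted p = 0.135. Against WT with SFB it also passed without WT replicate 3 with SFB (−0.40, adjusted p = 0.0229) and without IECΔCDC42 replicate 2 (−0.39, adjusted p = 0.0233). A value summed over the gene keeps reads from any exons outside the deleted part and from cells other than epithelium, so it checks the genotype labels only weakly. Which exons were deleted is not given in the sources used here.

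In WT mice, SFB colonization came with higher RNA of antimicrobial and acute-phase genes. Saa1, a serum amyloid A protein of the acute phase (chromosome 7, 46740497 to 46742980, minus strand), rose from 1459 ± 885 normalized counts (SD, n = 4) to 21671 ± 14894 (n = 3), a log2 fold change of 4.0 ± 0.89 (SE, adjusted p = 0.0431). Without replicate 3 of WT without SFB, where Saa1 was low, it was at 3.18 and did not pass, and it passed in 1 of 7 fits that left out a library. Reg3g (chromosome 6, 78466269 to 78468872, minus strand) and Reg3b, lectins that act on bacteria, rose by 1.73 ± 0.33 (adjusted p = 0.0265) and 1.30 ± 0.22 (adjusted p = 0.019). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254, plus strand), rose from 4832 ± 2524 to 22573 ± 1533 normalized counts (2.46 ± 0.48, adjusted p = 0.028). Duox2, an oxidase that makes hydrogen peroxide, and its maturation factor Duoxa2 rose by 1.38 ± 0.29 and 2.55 ± 0.39. With quantile normalization Reg3b was at 0.58 (adjusted p = 0.18).

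Of the 19 measured genes of the antimicrobial and acute-phase list, 11 rose and 0 fell. Antimicrobial and acute-phase genes had a median of 1.5, with 14 up and 2 down adjusted over the list alone. In camera, antimicrobial and acute-phase genes had adjusted p = 9.46e-10, and adjusted p = 0.375 with an estimated correlation. Saa3 (2.16 ± 0.25), Pla2g5 (2.66 ± 0.33) and Socs3 (1.5 ± 0.22), a feedback inhibitor of cytokine signalling, were among the risers, and Saa2 (3.98 ± 1.00, adjusted p = 0.0623) and Fut2 (1.49 ± 0.41, adjusted p = 0.0798), a fucosyltransferase, did not pass. Among cytokines and chemokines 4 of 20 rose, among them Ccl28 (1.32 ± 0.14) and Tnf (1.47 ± 0.25), and Il15 fell by 0.79. Cytokine and chemokine genes had a median of 0.18, with 6 up and 1 down adjusted over the list alone. In camera, cytokine and chemokine genes had adjusted p = 0.0275, and adjusted p = 0.418 with an estimated correlation. Cell death genes rose in 7 of 22 cases and fell in 0, with Casp4 (1.08 ± 0.13), an inflammatory caspase, and the necroptosis genes Mlkl (0.91 ± 0.12) and Ripk3 (0.60 ± 0.08), against 6 up and 2 down with library totals set equal. Cell death genes had a median of 0.37, with 13 up and 5 down adjusted over the list alone. In camera, cell death genes had adjusted p = 0.000612, and adjusted p = 0.431 with an estimated correlation. In the ER stress list, 3 of 20 rose, namely Xbp1 (0.40 ± 0.07), Sdf2l1 (0.51 ± 0.10) and the chaperone Hspa5 (0.58 ± 0.12). ER stress genes had a median of 0.24, with 8 up and 1 down adjusted over the list alone. In camera, ER stress genes had adjusted p = 0.00131, and adjusted p = 0.375 with an estimated correlation.

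Genes of antigen presentation and the interferon-γ response were also higher with SFB. In that list (MHC class I and interferon-γ targets) 10 of 24 genes rose and 0 fell, for example Nlrc5 (2.73 ± 0.62), a transactivator of MHC class I, and Irf1 (0.79 ± 0.11). MHC class I and interferon-γ genes had a median of 0.77, with 17 up and 0 down adjusted over the list alone. In camera, MHC class I and interferon-γ genes had adjusted p = 2.11e-13, and adjusted p = 0.418 with an estimated correlation. Of 10 MHC class II genes, 1 passed, the class II transactivator Ciita (2.80 ± 0.54), while H2-Aa (2.71 ± 0.65, adjusted p = 0.0543), H2-Ab1 (2.15 ± 0.64, adjusted p = 0.0972) and Cd74 (2.53 ± 0.68, adjusted p = 0.0735) did not. MHC class II genes had a median of 2.10, with 7 up and 0 down adjusted over the list alone. In camera, MHC class II genes had adjusted p = 0.000112, and adjusted p = 0.432 with an estimated correlation. Of 25 interferon-stimulated genes 4 rose, including Ifit1bl1 (1.97 ± 0.17) and the nucleic acid sensor Zbp1 (2.58 ± 0.41), and 1 fell, Ifi27l2b by 0.47. Interferon-stimulated genes had a median of 0.30, with 6 up and 2 down adjusted over the list alone. In camera, interferon-stimulated genes had adjusted p = 0.00154, and adjusted p = 0.517 with an estimated correlation. Markers of T cells and intraepithelial lymphocytes had 0 of 21 past the test and were called as a list. T cell genes had a median of 1.83, with 16 up and 0 down adjusted over the list alone. In camera, T cell genes had adjusted p = 2.73e-09, and adjusted p = 0.431 with an estimated correlation. The largest rises by the naming rule were Plet1 (4.61 ± 0.87), Saa1 (4.0 ± 0.89), B3galt5 (3.34 ± 0.77) and Ubd (3.02 ± 0.63). B and plasma cell markers rose in 3 of 14 cases, the antibody genes Igkc (1.36 ± 0.29), Jchain (1.25 ± 0.27) and Igha (1.37 ± 0.32). B and plasma cell genes had a median of 0.84, with 5 up and 0 down adjusted over the list alone. In camera, B and plasma cell genes had adjusted p = 0.000301, and adjusted p = 0.418 with an estimated correlation. Myeloid markers had 0 of 20 past the test. Myeloid genes had a median of 0.41, with 0 up and 0 down adjusted over the list alone. In camera, myeloid genes had adjusted p = 0.005, and adjusted p = 0.517 with an estimated correlation.

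Genes of connective tissue were lower with SFB. The stroma list fell in 11 of 16 cases, with Pdgfra (−1.61 ± 0.19), a fibroblast receptor, and the collagen Col6a1 (−1.97 ± 0.27). Without replicate 1 of WT without SFB 6 of its genes passed, with a median of −1.44. Stroma genes had a median of −1.71, with 0 up and 15 down adjusted over the list alone. In camera, stroma genes had adjusted p = 3.94e-13, and adjusted p = 0.375 with an estimated correlation. Endothelial markers fell in 1 of 10, Plvap (−1.65 ± 0.36), and enteric neuron and glia markers in 0 of 10. Endothelial genes had a median of −1.08, with 0 up and 8 down adjusted over the list alone. In camera, endothelial genes had adjusted p = 2.43e-05, and adjusted p = 0.418 with an estimated correlation. Enteric neuron and glia genes had a median of −0.51, with 0 up and 1 down adjusted over the list alone. In camera, enteric neuron and glia genes had adjusted p = 0.0294, and adjusted p = 0.418 with an estimated correlation. The largest falls were Nr0b2 (−4.98 ± 1.00), a nuclear receptor induced by bile acids, the nucleoside transporter Slc28a1 (−4.39 ± 0.51) and the hedgehog-binding protein Hhip (−3.69 ± 0.31). Angptl4, an inhibitor of lipoprotein lipase, fell from 4202 ± 677 to 907 ± 72.7 normalized counts (−2.2 ± 0.12, adjusted p = 0.000414), and Pdk4, a kinase that limits glucose oxidation, fell by 2.92. In the lipid absorption list these 2 of 20 fell. Lipid absorption genes had a median of −0.22, with 0 up and 3 down adjusted over the list alone. In camera, lipid absorption genes had adjusted p = 0.00165, and adjusted p = 0.375 with an estimated correlation. Clock genes fell in 4 of 19 cases, among them Nr1d1 (−2.68 ± 0.37) and Nr1d2 (−1.29 ± 0.15). Clock genes had a median of −0.38, with 0 up and 7 down adjusted over the list alone. In camera, clock genes had adjusted p = 0.0014, and adjusted p = 0.418 with an estimated correlation. Retinoid genes fell in 2 of 18, Cyp26b1 (−1.90 ± 0.31), which degrades retinoic acid, and Lrat (−0.97 ± 0.22). Retinoid genes had a median of −0.35, with 0 up and 6 down adjusted over the list alone. In camera, retinoid genes had adjusted p = 0.000253, and adjusted p = 0.375 with an estimated correlation. Brush border genes fell in 3 of 30, the sucrase-isomaltase Sis (−0.97 ± 0.17), the peptide transporter Slc15a1 (−0.66 ± 0.12) and the glucose transporter Slc2a2 (−2.33 ± 0.52). Brush border genes had a median of −0.09, with 1 up and 7 down adjusted over the list alone. In camera, brush border genes had adjusted p = 0.0275, and adjusted p = 0.606 with an estimated correlation. With a term for Y-linked RNA the brush border list was not called (adjusted p = 0.264) and 0 of its genes passed, with a median of 0.0043.

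Further lists were called with few or 0 single genes past the test. These were proliferation, tuft cells and Paneth cells. Proliferation genes had 0 up and 0 down of 25, with a median of 0.32 and 0 up and 0 down adjusted over the list alone. In camera, proliferation genes had adjusted p = 2.59e-05, and adjusted p = 0.517 with an estimated correlation. Tuft cell genes had 0 up and 0 down of 15, with a median of −0.37 and 0 up and 1 down adjusted over the list alone. In camera, tuft cell genes had adjusted p = 0.000346, and adjusted p = 0.467 with an estimated correlation. Paneth cell genes had 0 up and 0 down of 20, with a median of −0.33 and 0 up and 0 down adjusted over the list alone. In camera, Paneth cell genes had adjusted p = 0.0275, and adjusted p = 0.65 with an estimated correlation. Enteroendocrine genes were called lower, with Chga (−0.56 ± 0.12) falling and Tac1 (0.94 ± 0.21) rising. Enteroendocrine genes had a median of −0.21, with 1 up and 5 down adjusted over the list alone. In camera, enteroendocrine genes had adjusted p = 0.0275, and adjusted p = 0.418 with an estimated correlation. Xenobiotic genes were called lower with 1 of 23 past the test, Cyp1b1 (−2.49 ± 0.58). Xenobiotic genes had a median of −0.45, with 2 up and 6 down adjusted over the list alone. In camera, xenobiotic genes had adjusted p = 0.0046, and adjusted p = 0.436 with an estimated correlation. In the wound and regeneration list Ly6a rose (1.67 ± 0.34) and Krt23 fell (−0.82 ± 0.12). Wound and regeneration genes had a median of −0.37, with 1 up and 4 down adjusted over the list alone. In camera, wound and regeneration genes had adjusted p = 0.0346, and adjusted p = 0.431 with an estimated correlation. The lists for endocytosis, the CDC42 pathway and actin regulators were not called. Endocytosis genes had 0 up and 1 down of 37, with a median of −0.05 and 0 up and 2 down adjusted over the list alone (camera adjusted p = 0.169). CDC42 pathway genes had 1 up and 1 down of 36, with a median of −0.05 and 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.753). Actin regulator genes had 0 up and 0 down of 26, with a median of 0.02 and 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.833). With library totals set equal the actin regulator median turned to −0.041, and with quantile normalization to −0.025. Lyz1, the lysozyme of Paneth cells (−0.21 ± 0.25, adjusted p = 0.681), and Lgr5, a stem cell receptor (−0.39 ± 0.11, adjusted p = 0.0797), did not pass.

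In all, 781 of 19905 genes changed between WT with and without SFB (limma-trend), 366 up and 415 down, and 4130 had an unadjusted p under 0.05. With library totals set equal the split was 270 up and 638 down, while it turned to 316 up and 245 down without replicate 4 of WT without SFB and to 52 and 42 at adjusted p 0.01. With a term for Y-linked RNA, which separates replicates 1 and 2 with SFB from the other 5 libraries, 68 genes passed, 46 of them among the 781, and the effect of SFB then rests on replicate 3 alone, assumed to vary like the others. The medians with that term were 1.48 for antimicrobial genes (1 up), 1.10 for MHC class I and interferon-γ genes (2 up), 2.31 for T cell genes (0 up) and −1.40 for stroma (0 down). Of the 67 named genes that passed, 9 passed with that term, and Saa1 was at 4.53 (adjusted p = 0.222), Reg3g at 1.71 (adjusted p = 0.223) and Nos2 at 2.38 (adjusted p = 0.237). With library totals set equal Hspa5 was at 0.51 (adjusted p = 0.0519), Igha at 1.3 (adjusted p = 0.059) and Tac1 at 0.87 (adjusted p = 0.0577). The count fell to 347 without WT replicate 1 and 225 without WT replicate 3 of the group without SFB, and to 174 and 172 without replicates 2 and 3 of the group with SFB. Of these 67 genes, 23 passed in every such fit, among them Saa3, Pla2g5, Socs3, Irf1, Irgm1, Ifit1bl1, Ccl28, Casp4, Mlkl, Ripk3, Pdgfra, Pdgfrb, Nr1d1, Nr1d2, Angptl4, Pdk4 and Hhip. The highest adjusted p was 0.156 for Saa1 without replicate 2 with SFB, 0.0858 for Reg3g without replicate 3 with SFB, 0.0702 for Reg3b without replicate 3 with SFB, 0.0965 for Nos2 without replicate 2 with SFB and 0.141 for Duox2 without replicate 2 with SFB. Other splits of these libraries called up to 22 lists, against 23 for the real groups.

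Between IECΔCDC42 and WT libraries, both with SFB, the list with the largest median change was that of Paneth cell genes, which encode the antimicrobial products of small-intestinal crypts. All 20 measured genes of that list were lower in IECΔCDC42. Paneth cell genes had a median of −6.50, with 0 up and 20 down adjusted over the list alone. In camera, Paneth cell genes had adjusted p = 1.36e-136, and adjusted p = 0.16 with an estimated correlation. Lyz1, the lysozyme of Paneth cells (chromosome 10, 117287797 to 117292868, minus strand), fell from 304390 ± 79780.3 (SD, n = 3) to 28499.8 ± 6108 rescaled normalized counts (n = 3), a log2 fold change of −3.40 ± 0.33 (SE). Mptx2, a pentraxin (−8.55 ± 0.29), and the α-defensins Defa29 (−8.50 ± 0.32), Defa5 (−8.41 ± 0.35) and Defa30 (−8.24 ± 0.20) were among the 8 largest falls. Ang4, an antimicrobial ribonuclease, fell by 4.43 and Reg3a by 1.6.

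Other cell lineages differed too. Tuft cell genes fell in 13 of 15 cases, among them Sh2d6 (−2.88 ± 0.26) and Rgs13 (−2.95 ± 0.26) and Trpm5 (−2.61 ± 0.25), a cation channel. Tuft cell genes had a median of −2.01, with 0 up and 13 down adjusted over the list alone. In camera, tuft cell genes had adjusted p = 6.47e-11, and adjusted p = 0.338 with an estimated correlation. Goblet cell genes fell in 6 of 17 and rose in 1, with Muc2, the main gel-forming mucin, at −0.75 ± 0.16. Goblet cell genes had a median of −0.38, with 1 up and 7 down adjusted over the list alone. In camera, goblet cell genes had adjusted p = 0.00484, and adjusted p = 0.748 with an estimated correlation. In the stem cell list, Olfm4 (−4.62 ± 0.28) and Lgr5 (−2.57 ± 0.19; chromosome 10, 115450311 to 115587780, minus strand) fell and Prom1 rose (0.86 ± 0.18). Stem cell genes had 3 up and 7 down of 16, with a median of −0.44 and 3 up and 9 down adjusted over the list alone. In camera, stem cell genes had adjusted p = 0.00648, and adjusted p = 0.748 with an estimated correlation. Brush border genes included the fructose transporter Slc2a5 (−4.16 ± 0.38) and Slc15a1 (−2.29 ± 0.20), and with library totals set equal 20 fell. Brush border genes had 2 up and 15 down of 30, with a median of −0.44 and 3 up and 15 down adjusted over the list alone. In camera, brush border genes had adjusted p = 0.000436, and adjusted p = 0.625 with an estimated correlation. Enteroendocrine genes were not called as a list, with Chga (−1.06 ± 0.17) lower and Cck (1.21 ± 0.20) higher. Enteroendocrine genes had 1 up and 6 down of 17, with a median of −0.40 and 1 up and 6 down adjusted over the list alone. In camera, enteroendocrine genes had adjusted p = 0.159, and adjusted p = 0.579 with an estimated correlation. The villus tip and ileal bile acid lists were not called, and the bile acid-binding protein Fabp6 fell by 3.07. Villus tip genes had 4 up and 5 down of 14, with a median of −0.24 and 4 up and 5 down adjusted over the list alone (camera adjusted p = 0.54). Ileal bile acid genes had 2 up and 3 down of 14, with a median of 0.11 and 2 up and 3 down adjusted over the list alone (camera adjusted p = 0.619). The median of the bile acid list turned to −0.02 with library totals set equal and −0.06 with quantile normalization.

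Genes of wound repair and of the actin cytoskeleton were higher in IECΔCDC42. Anxa1, a phospholipid-binding protein of wound repair (chromosome 19, 20373428 to 20390944, minus strand), rose from 127 ± 28.4 to 19212 ± 2463 rescaled normalized counts (7.25 ± 0.22). The wound and regeneration list rose in 14 of 20 cases, with the EGF-family ligand Areg (4.91 ± 0.41) and the keratin genes Krt7 (2.23 ± 0.17) and Krt23 (2.89 ± 0.23). Wound and regeneration genes had a median of 2.14, with 14 up and 1 down adjusted over the list alone. In camera, wound and regeneration genes had adjusted p = 9.36e-17, and adjusted p = 0.16 with an estimated correlation. Actin regulators rose in 20 of 26, with the tropomyosin gene Tpm4 (1.53 ± 0.18) and Actr2 and Actr3 of the Arp2/3 complex (0.81 ± 0.12 and 0.79 ± 0.12). Actin regulator genes had a median of 0.63, with 21 up and 0 down adjusted over the list alone. In camera, actin regulator genes had adjusted p = 1.36e-09, and adjusted p = 0.338 with an estimated correlation. Genes of the CDC42 pathway rose in 18 of 36, among them Baiap2 (2.24 ± 0.16), Tnk2 (1.54 ± 0.12) and Rhoa (0.77 ± 0.10). CDC42 pathway genes had a median of 0.35, with 18 up and 4 down adjusted over the list alone. In camera, CDC42 pathway genes had adjusted p = 8.31e-06, and adjusted p = 0.402 with an estimated correlation. Endocytosis genes rose in 15 and fell in 4 of 37, with the recycling GTPase Rab11a (1.15 ± 0.13) and Cav2 (2.37 ± 0.34) up and the receptor genes Amn (−1.68 ± 0.21) and Cubn (−2.53 ± 0.37) down, and with library totals set equal the split was 9 and 5. Endocytosis genes had a median of 0.24, with 16 up and 4 down adjusted over the list alone. In camera, endocytosis genes had adjusted p = 0.0299, and adjusted p = 0.603 with an estimated correlation. Junction and polarity genes were not called as a list, with Cldn4 (1.87 ± 0.41) up and Cldn15 (−1.18 ± 0.12) down. Junction and polarity genes had 14 up and 2 down of 25, with a median of 0.32 and 15 up and 3 down adjusted over the list alone. In camera, junction and polarity genes had adjusted p = 0.0646, and adjusted p = 0.644 with an estimated correlation. That split was 12 and 4 with library totals set equal, and 10 and 4 with quantile normalization. The largest rises were Khdc1a (8.62 ± 0.96), Car1 (8.18 ± 1.94), Anxa1 (7.25 ± 0.22) and Cbr3 (7.07 ± 0.43), then the neutrophil chemokine Cxcl5 (6.44 ± 0.98) and the interleukin-1 receptor antagonist Il1rn (6.01 ± 0.52).

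Genes of T cells and of interferon-γ responses were lower in IECΔCDC42 than in WT with SFB. Gzmb, a protease of cytotoxic lymphocytes (chromosome 14, 56258838 to 56262260, minus strand), fell from 1563 ± 390.4 to 19.8 ± 8.30 rescaled normalized counts (−6.27 ± 1.25), and Cd8a by 4.24. The list of T cell and intraepithelial lymphocyte markers fell in 19 of 21 cases. T cell genes had a median of −3.22, with 0 up and 19 down adjusted over the list alone. In camera, T cell genes had adjusted p = 4.06e-06, and adjusted p = 0.579 with an estimated correlation. MHC class I and interferon-γ genes fell in 22 of 24, with B2m (−2.12 ± 0.26) and the immunoproteasome gene Psmb8 (−4.80 ± 0.53). MHC class I and interferon-γ genes had a median of −2.40, with 0 up and 22 down adjusted over the list alone. In camera, MHC class I and interferon-γ genes had adjusted p = 1.93e-19, and adjusted p = 0.402 with an estimated correlation. MHC class II genes fell in 7 of 10, with H2-Aa (−3.68 ± 0.88), H2-Ab1 (−3.51 ± 0.88) and Cd74 (−3.81 ± 0.94). MHC class II genes had a median of −3.60, with 0 up and 7 down adjusted over the list alone. In camera, MHC class II genes had adjusted p = 0.0158, and adjusted p = 0.603 with an estimated correlation. Interferon-stimulated genes fell in 21 of 25, with Zbp1 (−3.72 ± 0.49) and Ifit3 (−1.91 ± 0.22), and Oasl1 rose (1.86 ± 0.27). Interferon-stimulated genes had a median of −1.04, with 1 up and 21 down adjusted over the list alone. In camera, interferon-stimulated genes had adjusted p = 2.37e-06, and adjusted p = 0.561 with an estimated correlation. Markers of B and plasma cells and myeloid cells were not called as lists, and the neutrophil gene Ly6g rose by 5.43 ± 0.93. B and plasma cell genes had 1 up and 1 down of 14, with a median of −0.30 and 1 up and 1 down adjusted over the list alone (camera adjusted p = 1). Myeloid genes had 1 up and 2 down of 20, with a median of −0.40 and 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.619). With quantile normalization the B and plasma cell median was no longer below 0.

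Antimicrobial and acute-phase genes went both ways and were not called as a list. Antimicrobial and acute-phase genes had 4 up and 3 down of 19, with a median of 0.07 and 4 up and 3 down adjusted over the list alone. In camera, antimicrobial and acute-phase genes had adjusted p = 0.944, and adjusted p = 0.974 with an estimated correlation. Duox2 (1.38 ± 0.40, adjusted p = 0.00314) and Fut2 (1.85 ± 0.55, adjusted p = 0.00342) rose, and with a term for Y-linked RNA they were at 1.41 (adjusted p = 0.0999) and 1.75 (adjusted p = 0.0849). Both passed with that term in 1 fit over all libraries, where it cannot move the difference between these groups. The preset genes Saa1 (−0.85 ± 1.16, adjusted p = 0.648), Saa2 (−0.57 ± 1.33, adjusted p = 0.813), Reg3g (0.43 ± 0.41, adjusted p = 0.48), Reg3b (0.04 ± 0.29, adjusted p = 0.942) and Nos2 (0.10 ± 0.69, adjusted p = 0.942) did not pass. Cytokine and chemokine genes also went both ways, with Il33 (3.15 ± 0.28), an alarmin, up and Tnfsf10 (−4.49 ± 0.25) down. Cytokine and chemokine genes had 8 up and 7 down of 20, with a median of −0.02 and 8 up and 8 down adjusted over the list alone (camera adjusted p = 0.944). Cholesterol synthesis genes rose in 18 of 21 cases, with Fdps, an enzyme of that pathway (1.22 ± 0.12). Cholesterol synthesis genes had a median of 0.70, with 18 up and 1 down adjusted over the list alone. In camera, cholesterol synthesis genes had adjusted p = 1.36e-09, and adjusted p = 0.338 with an estimated correlation. With quantile normalization 15 rose and 2 fell. Xenobiotic genes rose in 11 and fell in 4 of 23, with the glutathione transferases Gsta1 (4.41 ± 0.29) and Gstm1 (4.05 ± 0.27) up and Cyp3a11 (−5.96 ± 0.85) down. Xenobiotic genes had a median of 0.73, with 11 up and 4 down adjusted over the list alone. In camera, xenobiotic genes had adjusted p = 0.00185, and adjusted p = 0.603 with an estimated correlation. Clock genes fell in 9 of 19 and rose in 3, with the period gene Per2 (−2.05 ± 0.23) down and Nr1d1 up (2.66 ± 0.57). Clock genes had a median of −0.70, with 4 up and 9 down adjusted over the list alone. In camera, clock genes had adjusted p = 0.0258, and adjusted p = 0.603 with an estimated correlation. Early response genes linked to tissue dissociation were called higher, with Ier3 (1.47 ± 0.21) and Fosl1 (3.39 ± 0.68). Whether handling raised them was not tested. Dissociation genes had 7 up and 1 down of 20, with a median of 0.35 and 7 up and 1 down adjusted over the list alone. In camera, dissociation genes had adjusted p = 0.0465, and adjusted p = 0.603 with an estimated correlation.

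Lists not called in this comparison were proliferation, lipid absorption, retinoid, ER stress and cell death, in which the gasdermin genes Gsdmc3 (−6.03 ± 0.44) and Gsdmc2 (−4.85 ± 0.36) fell. Proliferation genes had 2 up and 0 down of 25, with a median of 0.34 and 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.171). Lipid absorption genes had 4 up and 5 down of 20, with a median of −0.16 and 4 up and 6 down adjusted over the list alone (camera adjusted p = 1). Retinoid genes had 2 up and 5 down of 18, with a median of −0.35 and 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.234). ER stress genes had 4 up and 2 down of 20, with a median of 0.13 and 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.619). Cell death genes had 8 up and 7 down of 22, with a median of 0.11 and 10 up and 8 down adjusted over the list alone (camera adjusted p = 0.878). Nor were stroma, endothelium, enteric neurons and glia or pancreatic acinar genes. Stroma genes had 1 up and 0 down of 16, with a median of 0.02 and 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.656). Endothelial genes had 1 up and 1 down of 10, with a median of 0.20 and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.944). Enteric neuron and glia genes had 1 up and 0 down of 10, with a median of 0.26 and 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.626). Pancreatic acinar genes had 1 up and 1 down of 8, with a median of −0.37 and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.892). The mitochondrially encoded list and replication histones, which lack poly-A tails, were not called either. Mitochondrially encoded genes had 1 up and 0 down of 13, with a median of −0.06 and 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.927). Replication histone genes had 1 up and 0 down of 10, with a median of 0.08 and 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.717). With library totals set equal the medians of the antimicrobial, stroma and replication histone lists turned to −0.053, −0.11 and −0.045, ER stress genes to 2 up and 4 down, cell death genes to 7 up and 9 down (median −0.020) and cytokine genes to 8 up and 9 down, and 8 lipid absorption genes fell. With quantile normalization ER stress genes were at 3 up and 3 down, cell death genes at 7 up and 9 down (median −0.048), and the cytokine median turned to 0.24.

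In all, 6419 of 19605 genes changed between IECΔCDC42 and WT with SFB, 3328 up and 3091 down, from the difference of the limma-trend fits, and 7832 had an unadjusted p under 0.05. With library totals set equal 2235 rose and 3816 fell, and that scaling put the median of all genes at −0.13, from −0.012. At a log2 change of at least 1 there were 826 up and 1709 down. A t distribution for the difference of comparisons gave 4611 genes, with Calr and Atf3 not past the threshold. Only 1 library of each group with SFB, replicate 3, lacks Y-linked RNA. A term for Y-linked RNA in each table's fit therefore makes the effect rest on 1 library per group with SFB. With a term for Y-linked RNA 3772 genes passed, 1858 up and 1914 down, and Car1 was at 7.39 (adjusted p = 0.0677). In 1 fit over all libraries 7478 genes passed, and 7315 with that term added. All 127 named genes that passed in the main test passed with that term in 1 fit, Car1 included. Both groups with SFB hold the same number of libraries with Y-linked RNA. The term in 1 fit therefore cannot move the difference between them, and these calls do not test an effect of sex. In 1 fit over all libraries 18 lists were called, and other splits of these libraries called up to 22. Among named genes, Atf3 passed in 5 and Calr in 3 of the 10 fits that left out 1 library, with the highest adjusted p, 0.0976 without WT replicate 3 with SFB and 0.124 without WT replicate 1 with SFB.

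**Figure D2:**
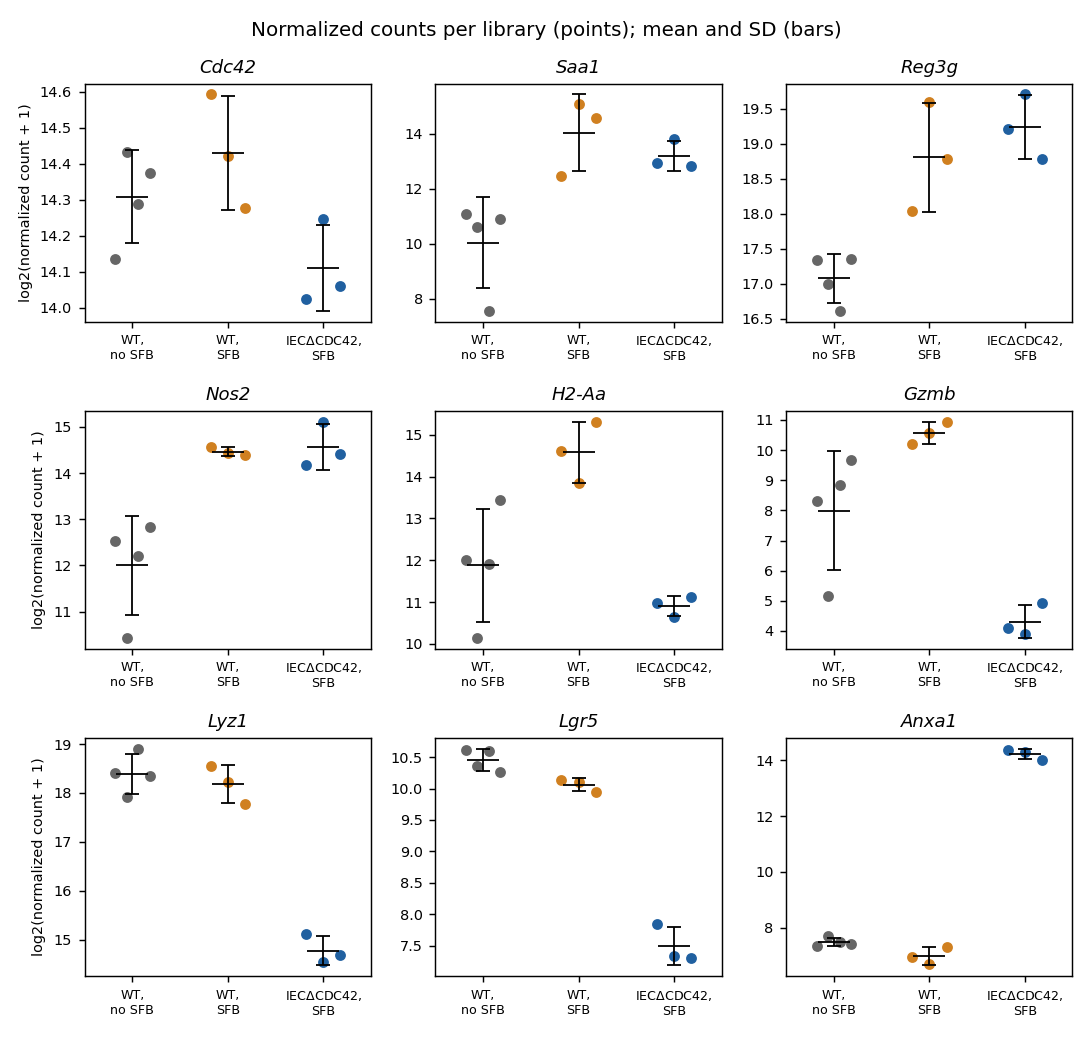
Levels of 9 genes per library as log2(normalized count + 1), with 1 point per library, the mean and SD as bars, for WT without SFB, WT with SFB and IECΔCDC42 with SFB (rescaled). Lyz1 and Gzmb are lowest and Anxa1 is highest in the 3 IECΔCDC42 libraries, and Saa1, Reg3g and Nos2 are higher in WT with SFB than in WT without.

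The second table sets IECΔCDC42 with SFB against WT without SFB, so genotype and colonization differ together. Paneth cell genes were lower in all 20 cases, with Lyz1 at −3.61 ± 0.22. Paneth cell genes had a median of −6.96, with 0 up and 20 down adjusted over the list alone. In camera, Paneth cell genes had adjusted p = 1.99e-20, and adjusted p = 0.366 with an estimated correlation. Antimicrobial and acute-phase genes rose in 14 and fell in 2 of 20, with Saa1 (3.15 ± 0.75), Saa2 (3.40 ± 0.87), Reg3g (2.16 ± 0.24), Reg3b (1.34 ± 0.19), Nos2 (2.56 ± 0.50), Duox2 (2.76 ± 0.28) and Fut2 (3.35 ± 0.36). Antimicrobial and acute-phase genes had a median of 2.2, with 14 up and 2 down adjusted over the list alone. In camera, antimicrobial and acute-phase genes had adjusted p = 0.00149, and adjusted p = 0.582 with an estimated correlation. With a term for Y-linked RNA Saa1 was at 2.79 (adjusted p = 0.121), Saa2 at 3.29 (adjusted p = 0.118) and Nos2 at 2.40 (adjusted p = 0.0565), while these 3 passed with that term in 1 fit. With quantile normalization Reg3b was at 0.10 (adjusted p = 0.611). MHC class I and interferon-γ genes fell in 18 of 24 and interferon-stimulated genes in 18 of 25, and T cell markers fell in 10 of 21, or in 6 with quantile normalization. MHC class I and interferon-γ genes had a median of −1.43, with 0 up and 19 down adjusted over the list alone. In camera, MHC class I and interferon-γ genes had adjusted p = 2.18e-06, and adjusted p = 0.636 with an estimated correlation. Interferon-stimulated genes had a median of −0.90, with 2 up and 18 down adjusted over the list alone. In camera, interferon-stimulated genes had adjusted p = 0.00102, and adjusted p = 0.676 with an estimated correlation. T cell genes had a median of −1.44, with 0 up and 11 down adjusted over the list alone. In camera, T cell genes had adjusted p = 0.00286, and adjusted p = 0.709 with an estimated correlation. With a term for Y-linked RNA 0 of them passed while their median was at −1.35, with Gzmb at −3.07 (adjusted p = 0.14) and Ccl5 at −3.05 (adjusted p = 0.123), and with that term in 1 fit 5 passed, Gzmb and Ccl5 among them. MHC class II was not called, and H2-Aa (−0.97 ± 0.59, adjusted p = 0.218), H2-Ab1 (−1.37 ± 0.61, adjusted p = 0.096) and Cd74 (−1.28 ± 0.65, adjusted p = 0.143) did not pass. MHC class II genes had 0 up and 1 down of 10, with a median of −0.98 and 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.253). The largest rises were Syt8 (8.89 ± 0.51), Car1 (8.4 ± 1.34), Khdc1a (8.25 ± 0.57) and Plet1 (7.53 ± 0.33), and the largest falls included Cyp3a11, a drug-metabolizing enzyme (−8.82 ± 0.51). Without replicate 2 of WT without SFB, where Car1 was high, its rise was 9.92.

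Further lists called lower in that comparison were those of other epithelial lineages, with the tuft cell genes Sh2d6 (−3.27 ± 0.17) and Trpm5 (−2.92 ± 0.20), the stem cell gene Olfm4 (−4.92 ± 0.24) and the sugar transporter Slc2a5 (−4.97 ± 0.29). These were tuft, enteroendocrine, stem cell and brush border genes. Tuft cell genes had 0 up and 14 down of 15, with a median of −2.49 and 0 up and 14 down adjusted over the list alone. In camera, tuft cell genes had adjusted p = 4.11e-08, and adjusted p = 0.477 with an estimated correlation. Enteroendocrine genes had 2 up and 9 down of 17, with a median of −0.46 and 2 up and 9 down adjusted over the list alone. In camera, enteroendocrine genes had adjusted p = 0.00856, and adjusted p = 0.51 with an estimated correlation. Stem cell genes had 3 up and 10 down of 16, with a median of −0.79 and 3 up and 10 down adjusted over the list alone. In camera, stem cell genes had adjusted p = 0.0149, and adjusted p = 0.709 with an estimated correlation. Brush border genes had 3 up and 19 down of 30, with a median of −0.63 and 4 up and 19 down adjusted over the list alone. In camera, brush border genes had adjusted p = 0.000255, and adjusted p = 0.676 with an estimated correlation. Lgr5 fell by 2.96. Rises included the mitotic gene Birc5 (1.02 ± 0.16), Anxa1 (6.75 ± 0.12) and Areg (4.90 ± 0.28), the tropomyosin gene Tpm4 (1.51 ± 0.12) and Fdps of cholesterol synthesis (1.27 ± 0.09). Proliferation (8 rose with library totals set equal), wound, actin, CDC42 pathway, cholesterol, ER stress and B and plasma cell genes were called higher. Proliferation genes had 15 up and 0 down of 25, with a median of 0.53 and 17 up and 0 down adjusted over the list alone. In camera, proliferation genes had adjusted p = 9.7e-05, and adjusted p = 0.709 with an estimated correlation. Wound and regeneration genes had 13 up and 2 down of 20, with a median of 1.58 and 14 up and 3 down adjusted over the list alone. In camera, wound and regeneration genes had adjusted p = 4.96e-05, and adjusted p = 0.477 with an estimated correlation. Actin regulator genes had 20 up and 1 down of 26, with a median of 0.59 and 21 up and 1 down adjusted over the list alone. In camera, actin regulator genes had adjusted p = 7.57e-07, and adjusted p = 0.55 with an estimated correlation. CDC42 pathway genes had 19 up and 6 down of 36, with a median of 0.33 and 19 up and 6 down adjusted over the list alone. In camera, CDC42 pathway genes had adjusted p = 0.00246, and adjusted p = 0.582 with an estimated correlation. Cholesterol synthesis genes had 17 up and 2 down of 21, with a median of 0.74 and 17 up and 3 down adjusted over the list alone. In camera, cholesterol synthesis genes had adjusted p = 3.76e-06, and adjusted p = 0.51 with an estimated correlation. ER stress genes had 11 up and 4 down of 20, with a median of 0.40 and 12 up and 4 down adjusted over the list alone. In camera, ER stress genes had adjusted p = 0.0233, and adjusted p = 0.636 with an estimated correlation. B and plasma cell genes had 7 up and 0 down of 14, with a median of 0.65 and 7 up and 0 down adjusted over the list alone. In camera, B and plasma cell genes had adjusted p = 0.0192, and adjusted p = 0.676 with an estimated correlation. B and plasma cell genes rose in 4 cases with library totals set equal and in 10 with quantile normalization. Retinoid, clock, stroma and endothelial genes were called lower. Retinoid genes had 1 up and 10 down of 18, with a median of −0.68 and 1 up and 11 down adjusted over the list alone. In camera, retinoid genes had adjusted p = 0.00581, and adjusted p = 0.55 with an estimated correlation. Clock genes had 2 up and 13 down of 19, with a median of −0.64 and 2 up and 13 down adjusted over the list alone. In camera, clock genes had adjusted p = 0.000998, and adjusted p = 0.51 with an estimated correlation. Stroma genes had 0 up and 15 down of 16, with a median of −1.27 and 0 up and 15 down adjusted over the list alone. In camera, stroma genes had adjusted p = 9.7e-05, and adjusted p = 0.636 with an estimated correlation. Endothelial genes had 1 up and 6 down of 10, with a median of −0.92 and 1 up and 8 down adjusted over the list alone. In camera, endothelial genes had adjusted p = 0.0349, and adjusted p = 0.709 with an estimated correlation. Of clock genes 0 rose under either of these scalings. Endocytosis genes were not called, with 18 up and 6 down of 37, and this split turned to 7 and 11 with library totals set equal and 8 and 10 with quantile normalization. In all, 9096 of 19938 genes changed, 4723 up and 4373 down (limma-trend), against 2991 up and 5727 down with library totals set equal, a scaling that put the median of all genes at −0.22, from −0.038. At a log2 change of at least 1 it was 1205 up and 2406 down. A term for Y-linked RNA in this table's fit makes the effect rest on replicate 3 of IECΔCDC42 alone. With a term for Y-linked RNA 4886 passed, and 6981 with that term in 1 fit over all libraries, where 143 of 147 named genes kept their call. Other splits of these libraries called up to 23 lists, against 20 for the real groups.

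**Figure D3:**
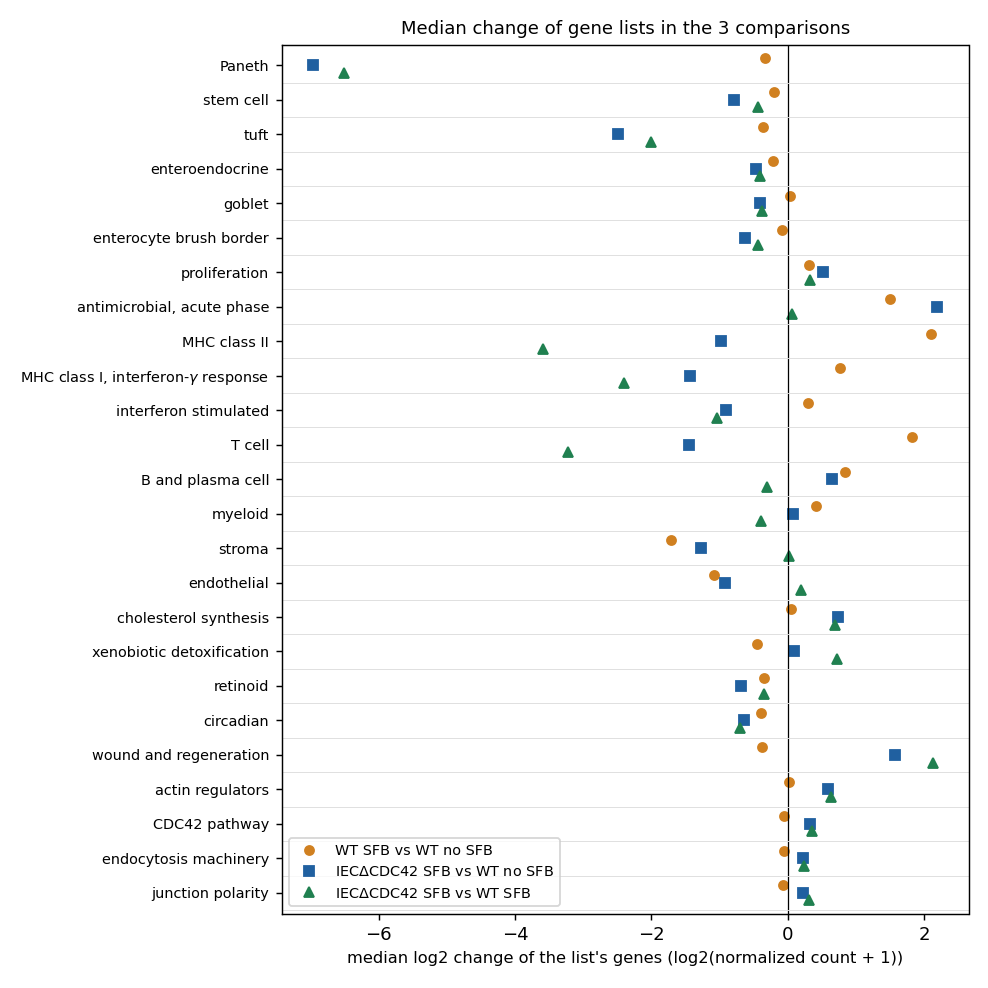
Median log2 fold change of 25 gene lists, 1 point per list and comparison, for WT with against without SFB, IECΔCDC42 with SFB against WT without, and IECΔCDC42 against WT with SFB. Paneth genes sit at −6.96 and −6.50 in the comparisons with IECΔCDC42, and T cell genes at 1.83 with SFB in WT and −3.22 in IECΔCDC42 against WT with SFB.

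Of the 359 genes that rose with SFB in WT and were tested in both tables, 232 were also higher in IECΔCDC42 with SFB than in WT without and 47 were lower. Of the 415 that fell, 314 were also lower and 27 were higher. Both tables use the same 4 libraries without SFB, which alone makes calls coincide, and the overlap that this gives was not tested. Against WT with SFB, 93 of the 359 were lower in IECΔCDC42, 113 were higher and 153 did not pass, and of the 415, 76 were higher, 131 lower and 208 did not pass. These counts reuse the WT libraries with SFB by which the genes were picked. Across the 19605 genes, which are not independent replicates, the log2 fold changes of the tables correlated at r = 0.407. Data simulated with no effect but shared controls gave r = 0.427 (highest of 100 draws 0.464). The simulation held no effects, while effects widen the spread of the real changes. Its r therefore cannot show how much of the observed r comes from shared controls. The covariance was 0.279 against 0.0569 simulated, and with separate controls for each comparison r was 0.177 to 0.343.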

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

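The tests of Paneth, T cell and stroma patterns below were chosen after the values had been seen, and the counts of other splits were planned before. Of 48 genes examined in the 4 WT libraries without SFB, 4 had 1 library far from the other 3 on the log2 scale (gap over range above Dixon's critical value), and chance gives about 1 in 20. Saa1 was at 187 normalized counts in replicate 3, against 1557 to 2172 in the others, and without that library its change against WT without SFB was 3.18 in WT (4.0 with it) and 2.32 in IECΔCDC42 (3.15 with it). B3galt5 was at 199 in replicate 4, against 71.1 to 81.0, and its rise in WT did not pass without that library. Car1 was at 7084 in replicate 2, against 73.9 to 151, and without that library its change in IECΔCDC42 was 9.92 (8.4 with it). Cxcl5 was at 1.04 in replicate 3, against 5.71 to 7.37.

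Paneth cell genes were lower in IECΔCDC42 than in WT with SFB, with a median of −6.50. If large intestine had been taken in place of small intestine, 5 bile acid genes were predicted to fall far, and their median was 0.079. Of these 5 genes 1 passed, Fabp6, which fell by 3.07. How far each gene is limited to small intestine was not examined, so this median does not decide the question. If fewer crypt cells of every kind had been recovered, proliferation genes would be lower too, and their median was 0.34 with 2 up and 0 down of 25. The stem cell list had a median of −0.44 with 7 of 16 lower, among them Olfm4 (−4.62) and Lgr5 (−2.57), so a loss limited to cells of the crypt base is not excluded. Reads shared among α-defensin copies would leave other Paneth genes in place, and the 9 that are not α-defensins had a median of −3.40, with 9 of 9 lower. A loss of Paneth cells or of their products with the Cdc42 deletion may account for the pattern, as a hypothesis found and examined in the same data. The series holds no IECΔCDC42 library without SFB. An effect of the deletion itself therefore cannot be told apart from one that needs SFB, here or for the T cell and interferon-γ genes.

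T cell and interferon-γ genes were lower in IECΔCDC42 than in WT with SFB. Fewer leukocytes of every kind would lower the other leukocyte lists alike, and the medians were −0.30 for B and plasma cells and −0.40 for myeloid cells against −3.22 for T cells, whose quartiles were −4.16 and −2.52. High values of the WT libraries with SFB alone would leave the IECΔCDC42 libraries level with WT without SFB, and there the interferon-γ list had a median of −1.43 with 18 genes lower. T cell genes had a median of −1.44 there, with 10 of 21 lower. Their median with SFB in WT was 1.83, with 0 of 21 past the test. High values of WT with SFB may thus account for part of the fall of T cell genes. Fewer intraepithelial T cells, a weaker interferon-γ response, or both may be involved, and which of them was not tested. The sex of the animals does not differ in number between these groups by Y-linked RNA.

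Stroma genes were lower in both groups with SFB than in WT without, by a median of −1.71 in WT and −1.27 in IECΔCDC42. Fewer connective tissue and vessel cells carried over would lower endothelial and glial lists as well, and the highest of their medians was −0.22, with −1.08 and −0.92 for endothelium, so this explanation stays open, although with quantile normalization the glial median in IECΔCDC42 was 0.22. Sex as the whole cause is set against a stroma median of −1.48 in WT and −1.07 in IECΔCDC42 with a term for Y-linked RNA in 1 fit. The control library richest in smooth muscle RNA, replicate 1 of WT without SFB, is set against medians of −1.44 (6 genes lower) and −1.15 (13 genes lower) without it. An effect of SFB on connective tissue could also contribute and was not tested.

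Other splits of the same libraries were counted. For WT with against without SFB, 1 of 35 splits, the real one, gave 781 genes, and the highest other gave 4. That is the smallest share that 35 splits can give, so chance is unlikely but not excluded for the gene count. For IECΔCDC42 with SFB against WT without, 1 of 35 gave 9096, and the highest other gave 9. For gene lists, 1 of 35 splits gave the 23 lists of the former comparison with 22 the highest other, and 5 of 35 gave the 20 of the latter or more, with 23 the highest other, so chance is not excluded there. For IECΔCDC42 against WT with SFB, in 1 fit over all libraries, the real split gave 7478 genes (1 of 10 splits, highest other 3) and 18 lists (3 of 10 splits, highest other 22), and 10 splits are too few to reach a share under 0.05. Splits that mix the groups thus also call many lists at the preset correlation.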

How the results depend on the processing

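The term for Y-linked RNA, the restriction to libraries without it, the single fit over all libraries, limma without trend and quantile normalization were chosen after seeing the data. Only 1 library of each group with SFB lacks Y-linked RNA. The restriction leaves only that library in such a group, so the spread within the group cannot be estimated. The gene counts with this restriction therefore rest on 1 library per group with SFB, and no conclusion is drawn from them. The term within 1 table makes the effect rest on that library too. Where a value below moved, the cause was not tested. The count of genes changed with SFB in WT (781) was 68 with a term for Y-linked RNA, 84 with libraries without Y-linked RNA only, 136 with that term in 1 fit, 77 without trend, 94 at adjusted p 0.01, 384 with a log2 change of at least 1, 4130 at unadjusted p 0.05, and 172 to 897 leaving out 1 library. For IECΔCDC42 with SFB against WT without (9096) it was 4886 with the term, 6981 with the term in 1 fit, 5080 without Y-linked libraries, 3611 with a log2 change of at least 1 (1205 up, 2406 down), and 7805 to 8780 leaving out 1 library. For IECΔCDC42 against WT with SFB (6419) it was 3772 with the term, 4611 with a t distribution for the difference and 7478 in 1 fit. Adding the term to that fit gave 7315, where it cannot move the difference between these groups. The count was 2535 with a log2 change of at least 1 (826 up, 1709 down), and 5656 to 6352 leaving out 1 library. Gene lists called (23, 20 and 17) fell to 0 in each comparison with an estimated correlation (in 1 fit for the last), and to 5 with fry for SFB in WT; leaving out 1 library gave 17 to 25, 19 to 23 and 15 to 18. Cdc42 passed the test with library totals set equal (−0.39 against WT without SFB, −0.44 against WT with SFB), with quantile normalization (−0.43 and −0.47), and against WT with SFB in 1 fit (−0.32, also −0.32 with the Y term). Leaving out 1 library Cdc42 was at 0.04 to 0.20, −0.27 to −0.15 and −0.40 to −0.24 in the 3 comparisons. The correlation of the comparisons (0.407) was 0.300 with the Y term, 0.302 without Y-linked libraries, 0.444 with that term in 1 fit, 0.486 over genes called in either, 0.271 with split controls and 0.356 to 0.454 leaving out 1 library. Of the named genes that passed, 0 changed sign, and the other genes called were not examined for this. Cdc42 with SFB in WT, which did not pass, was at −0.032 with the Y term. Under other settings the median or the balance of up and down turned for some lists, and so did the balance of all genes called. In both comparisons with IECΔCDC42 it turned with library totals set equal (2991 and 5727, 2235 and 3816) and with a log2 change of at least 1. Against WT with SFB it also turned with the Y term (1858 and 1914) and without trend (3095 and 3177). For SFB in WT it turned with the Y term (37 and 31), with that term in 1 fit (80 and 56), at adjusted p 0.01 (52 and 42), and without replicate 3 (115 and 110) or 4 (316 and 245) of WT without SFB. Of the other values of named genes, 1852 kept their side of the threshold for SFB in WT, 431 lost it and 54 gained it. These counts were 2969, 46 and 5 for IECΔCDC42 against WT without SFB and 3140, 40 and 5 against WT with SFB. Of the single-list values 736, 773 and 875 kept their side, 74, 36 and 46 lost it and 18, 19 and 15 gained it in the 3 comparisons. No paired analysis was possible because the replicate numbers give only the order of the samples. DESeq2, edgeR size factors and limma-voom were not run because the values are normalized and not whole, and no adjusted p is in the tables. At a simulated fold of 2, 57.1 to 69.4% of changed genes were recovered with these numbers of libraries, in data with independent genes. How depth limits this was not tested because read counts were not recovered.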

Other observations

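The groups of genes below were chosen after their values had been seen, so their tests are not independent evidence, and all values compare IECΔCDC42 with WT, both with SFB, unless stated. Glycolysis genes rose in 17 of 20 cases, among them the glucose transporter Slc2a1 (2.60 ± 0.17), the pyruvate kinase Pkm (1.71 ± 0.14) and the lactate dehydrogenase Ldha (1.14 ± 0.15) (median 1.08, 17 up and 0 down adjusted over the list alone, camera adjusted p = 1.01e-15, adjusted p = 0.0693 with an estimated correlation). Genes of glutathione and the NRF2 oxidant response rose in 20 of 21, with the cystine transporter Slc7a11 (3.24 ± 0.23), Gclc, which starts glutathione synthesis (1.45 ± 0.17), and Txnrd1 (1.00 ± 0.12) (median 1.10, 20 up and 0 down adjusted over the list alone, camera adjusted p = 4.35e-22, adjusted p = 0.0239 with an estimated correlation). Against WT without SFB these were 18 up and 1 down, median 1.43 for glycolysis and 20 up and 0 down, median 1.52 for glutathione genes. With SFB in WT glycolysis genes rose in 4 of 20 cases (median 0.30, 12 up and 0 down adjusted over the list alone, camera adjusted p = 8.35e-08, adjusted p = 0.436 with an estimated correlation).

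Of 25 genes listed with the cornified envelope, better known from skin, 20 were tested and 11 rose, with Ly6d (5.82 ± 0.54) and Sprr1a (3.36 ± 0.77) (median 1.85, 13 up and 0 down adjusted over the list alone, camera adjusted p = 1.96e-07, adjusted p = 0.0693 with an estimated correlation). The other 9 did not pass, among them the transglutaminase Tgm1 (0.50 ± 0.75) and the keratin genes Krt5 (0.77 ± 1.58) and Krt14 (0.19 ± 0.79), so the rise covers only part of the list. The 4 gasdermin C genes all fell, with Gsdmc at −5.79 ± 0.56 (median −5.32). With SFB in WT the median of these 4 genes was 0.76, and 1 passed, Gsdmc2 (0.78 ± 0.17), while the other 3 did not (4 up and 0 down adjusted over the list alone). Against WT without SFB their median in IECΔCDC42 was −4.52. Targets of hypoxia-inducible factors rose in 7 and fell in 3 of 16, with Adm at 1.67 ± 0.34 and Vegfa at −0.91 ± 0.24 (median 0.55, 8 up and 3 down adjusted over the list alone, camera adjusted p = 0.000216, adjusted p = 0.157 with an estimated correlation). Ribosomal protein genes rose in 7 of 26 (median 0.23, 6 up and 0 down adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.323 with an estimated correlation). Immunoglobulin variable segments, a sign of plasma cells, rose in 36 of 191 cases with SFB in WT (median 1.71), in 46 of 183 in IECΔCDC42 with SFB against WT without (median 1.18), and in 1 of 180 in IECΔCDC42 against WT with SFB, where 7 fell (median −0.44).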
